A study of Mus musculus with 2 samples.

How the data were processed

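Gene expression was measured in 2 samples of mouse spleen CD4 T cells, 1 array for IL-5+ and 1 for IL-5- memory Th2 cells. Per the labels' protocols, CD4 T cells were purified magnetically to over 98%, cultured for 6 days with 25 U/ml IL-2, 100 U/ml IL-4 and an ovalbumin peptide, transferred, recovered from the spleen after 30 days and separated by flow sorting. The labels do not give the number of recipients, whether RNA was pooled, or how the cells were stimulated and stained before the sort. RNA was labelled with biotin for Affymetrix arrays.

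The authors deposited 1 signal intensity per probe set and array, made with GCOS (the Affymetrix scanner software) per the submitters' processing notes. Its version, algorithm and scaling target are not given in the sources used here. The deposited intensity values are linear, from 0.1 to 51950, and hold no detection calls. The mean signal without the lowest and highest 2% was 496 on the IL-5+ and 497 on the IL-5- array, as global scaling to a common target would give, and the medians were 57.2 and 60.4. Such scaling removes differences in total RNA yield, so every ratio is relative to the rest of the array. Affymetrix control probe sets, from which RNA integrity could be judged, were not analysed here. Array signals near background and near saturation are compressed, and the brightest probe sets, including those of Il5, Il4 and Il13, lie close to the top of the range.

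Of 45037 probe sets, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed and stayed unnamed. The entrez identifiers of 34741 matched a RefSeq gene table of GRCm38.p6, which changed no symbol. No genome build is named for the deposited values, so no coordinates are given. Each of the 18193 genes was represented by its probe set with the highest mean log2 signal, a choice blind to the ratio. Signals under the floor, the 40th percentile of all signals (36.3), were set to it. A gene above the floor on 1 array only has a bound ("at least"), and 5060 genes under it on both have no ratio. The result per gene is the log2 ratio of signals, IL-5+ over IL-5-. With 1 array per group there was no test, and a gene was counted as higher or lower at a 2-fold difference.

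The named genes follow a rule written before the data were examined. It took 18 genes of Th2 and memory biology, of which 2 have no named probe set and were not analysed here. It took the 12 highest and 12 lowest ratios among genes measured on both arrays and the 5 largest bounds each way, where no other measured probe set had the opposite sign. It also took up to 4 members with the largest ratio from each of 33 gene lists, and the 2 brightest members of lists of other cell types. The lists hold 401 different genes, 45 of which had no named probe set, and 11 genes stand in more than 1 list. The median ratio of each list with at least 4 members above the floor was ranked among 10000 random lists drawn from 20 brightness bins. No p-value was computed. The cause of dim signals cannot be read from the table, and the number of arrays limits the precision.

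Counting and list ranking were tested on simulated arrays with the observed spread over 18193 genes. Of 100 planted genes changed by 1.5 on the log2 scale, 91% were called in the right direction, and of 100 changed by 3, all (100%). The planted genes were drawn from those above the floor on both arrays. The list of housekeeping genes, which are bright, reached the 100th percentile when shifted by 0.5, and 1 unshifted list stood apart. A shift of dim lists was not tried. For some of these the 98th percentile of random lists lay above 0.5, such as 0.54 for neutrophil markers. Alternatives fixed beforehand were 3 other scalings (array median, quantile, loess), floors at the 20th and 60th percentile or none, an added constant, the median of a gene's probe sets, only probe sets without the suffixes _s_at, _x_at and _a_at, and thresholds of 1.5-fold and 3-fold. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.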

Results

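The study compared memory T helper 2 (Th2) cells that produced interleukin-5 with memory Th2 cells that did not. CD4 T cells carrying the DO11.10 transgenic T cell receptor, which recognises an ovalbumin peptide, were cultured under Th2 conditions with IL-2 and IL-4 for 6 days and moved into athymic BALB/c nu/nu recipients. After 30 days the memory cells were recovered from the spleen and sorted into IL-5+ and IL-5- fractions. RNA from each fraction was hybridised to 1 Affymetrix mouse array, so the data were 2 arrays, 1 per group. No difference below therefore has a replicate check or a p-value, and each ratio describes these 2 RNA samples. The only error that could be measured was the disagreement between different probe sets of the same gene. The SD of the log2 ratio between such probe sets was 0.55 at mean signals from 36.3 to 112.8, 0.37 from there to 500, 0.21 from 500 to 2000 and 0.13 above 2000. This SD leaves out the variation between cell preparations.

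The sorted fractions differed in the sorting marker by more than in any other gene. Il5 had a signal of 37085 on the IL-5+ array and 67.4 on the IL-5- array, a 550-fold difference (log2 ratio 9.10). The IL-5- signal lay above the floor of 36.3 used here but under 112.8, the level that 60% of all signals stayed below, and with a floor of 112.8 the log2 ratio was 8.36. Among the genes chosen before the data were examined, the Th2 cytokines Il4 and Il13 were 3.35-fold and 6.19-fold higher in IL-5+ cells. Gata3, the transcription factor that directs Th2 differentiation, had signals of 5968 and 3570 in IL-5+ and IL-5- cells (log2 ratio 0.74). The nuclear receptor genes Pparg and Rora were higher by 2.66 and 2.21 on the log2 scale, although the 7 measured Rora probe sets ranged from 0.55 to 2.65. In the opposite direction, the T-box factor genes Eomes (641 against 1472) and Tbx21 (1053 against 2971) were lower in IL-5+ cells, by 2.30-fold and 2.82-fold. Both measured Eomes probe sets gave this direction, at -1.52 and -1.20. Ccr7, the receptor that guides T cells to lymph nodes, was lower by a log2 ratio of -2.27. Ifng (-0.34), Cxcr3 (-0.83), Cd44 (0.47) and Il7r (-0.040) differed by less than 2-fold. Ccr8 had a log2 ratio of 1.06, which was 0.99 with a floor of 112.8 and 0.86 with an added constant. Ptgdr2 was under the floor on both arrays, and Il17rb was above it only on the IL-5- array, at 65.4, which is still under 112.8.

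**Figure D1:**
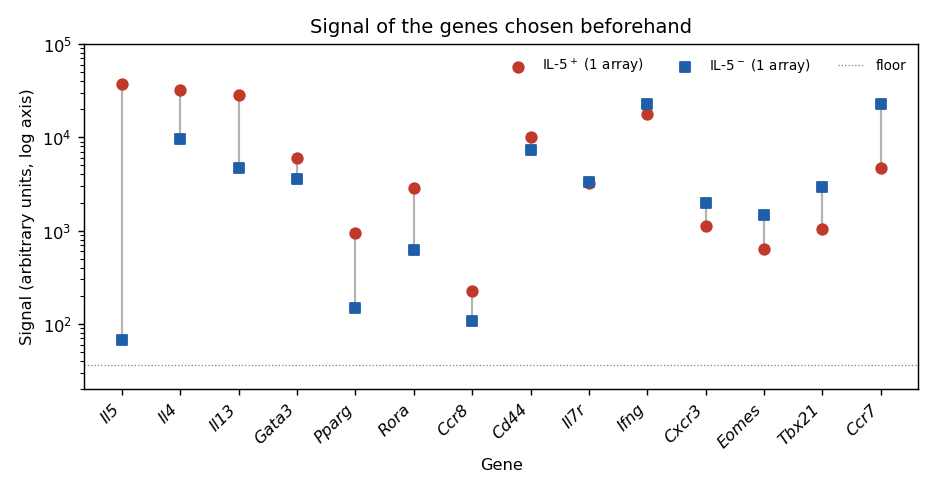
Signal (arbitrary units, log axis) of 14 of the genes chosen beforehand on the IL-5+ array (circles) and the IL-5- array (squares), with 1 array per group and a dotted line at the floor of 36.3. Il5 has the widest gap, from 67.4 to 37085, and Eomes, Tbx21, Cxcr3, Ifng and Ccr7 lie lower on the IL-5+ array.

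Across the array, 13133 named genes were above the floor on 1 or both arrays. Of these, 374 (2.85%) were at least 2-fold higher and 526 (4.01%) at least 2-fold lower in IL-5+ cells. The size of the excess of lower genes depended on scaling. It was nearly absent when each array was divided by its median (435 higher and 443 lower). Quantile scaling gave 415 higher and 463 lower, and loess gave 405 and 469. The 900 genes included 287 whose brighter signal was 500 or more, 136 of them higher and 151 lower, and 295 whose brighter signal stayed under 112.8. Simulated arrays with no change, drawn with the observed spread of ratios over 18193 genes, gave 393 higher and 396 lower genes. Of those simulated calls, 22 had a brighter signal of 500 or more. The bright calls, 287 against 22, exceeded what normal errors of the observed spread gave. That spread includes any true differences, which raises the simulated counts. Variation between cell preparations was not measured, so neither the total counts nor the bright genes are shown to exceed that variation. The totals were 1325 higher and 1572 lower with a floor at the 20th percentile of signals, and 183 and 226 with a floor at the 60th.

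The 12 genes with the highest ratios among those measured on both arrays without an opposite-sign probe set included 6 cytokine or nuclear receptor genes. After Il5 came Il9 (9277 against 547, log2 ratio 4.08), a mast cell and mucosal Th2 cytokine, and Il31 (922 against 95.4, 3.27), a cytokine linked to itch. Il6, Il13 and Pparg completed that group at 2.51, 2.63 and 2.66. The others were Hc (complement component C5, 3.04), Csgalnact1 (2.87), Plin2 (a lipid droplet coat protein, 2.76), Pcdh19 (2.75), Tpbg (2.75) and Ccdc184 (2.71). Tpbg had 3 probe sets, from 2.06 to 2.84. Like that of Il5, the IL-5- signals of Il31, Il6, Hc, Csgalnact1, Plin2 and Pcdh19 lay under 112.8, from 40.5 for Pcdh19 to 111 for Plin2. With a floor of 112.8 the ratios of these genes are smaller. Of the 3 Pcdh19 probe sets, 1 was above the floor on both arrays. Among genes above the floor on the IL-5+ array alone, Hdc, the histamine-forming enzyme, was at least 9.72-fold higher (353 against 10.4). It was followed by Depdc7 (at least 6.93-fold), Serpinb1a (log2 bound 2.63), Ltb4r1, a leukotriene B4 receptor (at least 5.05-fold), and Sgms2 (at least 4.84-fold). With a floor of 112.8 the log2 bounds of Serpinb1a, Ltb4r1 and Sgms2 were below 1, and a second Sgms2 probe set measured on both arrays gave 0.34.

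The 12 lowest ratios were taken from genes measured on both arrays without a probe set of opposite sign, which left out Ighm (-3.66). Of the 12, 6 belonged to genes known to be induced by interferon. Actn1, an actin cross-linker, had the lowest ratio (67.8 against 1643, log2 ratio -4.60). It was followed by Klf2 (275 against 3323, -3.60), a transcription factor of quiescent T cells. The interferon-induced genes Iigp1 (-3.57), Ifit3 (-3.57), Mx1 (-3.51), Cxcl10 (-3.30), Gbp2b (-3.30) and Gbp2 (-3.12) were among the 12, together with Aff3 (-3.46), Myo6 (-3.45), Igf1r (-3.19) and Klrb1f (8.02-fold lower). Both probe sets of Iigp1 and of Gbp2 lay below -3. Aff3 and Igf1r each had a probe set with a much smaller difference, at -0.61 and -0.33. The IL-5+ signals of Actn1, Ifit3, Mx1, Cxcl10, Aff3, Igf1r and Klrb1f lay under 112.8, from 53.4 for Klrb1f to 101.9 for Cxcl10. With a floor of 112.8 the differences of these genes are smaller. Of the 3 Actn1 probe sets, 1 was above the floor of 36.3 on both arrays. Of the 1165 genes above the floor on the IL-5- array alone, those with the largest bounds were Gm4951 (at least 22.8-fold lower in IL-5+ cells), Spsb1 (at least 11.7-fold), Esm1 (at least 7.52-fold), Tbxa2r (at least 7.21-fold) and the interferon-induced Mx2 (at least 7.15-fold). Another Spsb1 probe set, measured on both arrays, gave -0.69.

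**Figure D2:**
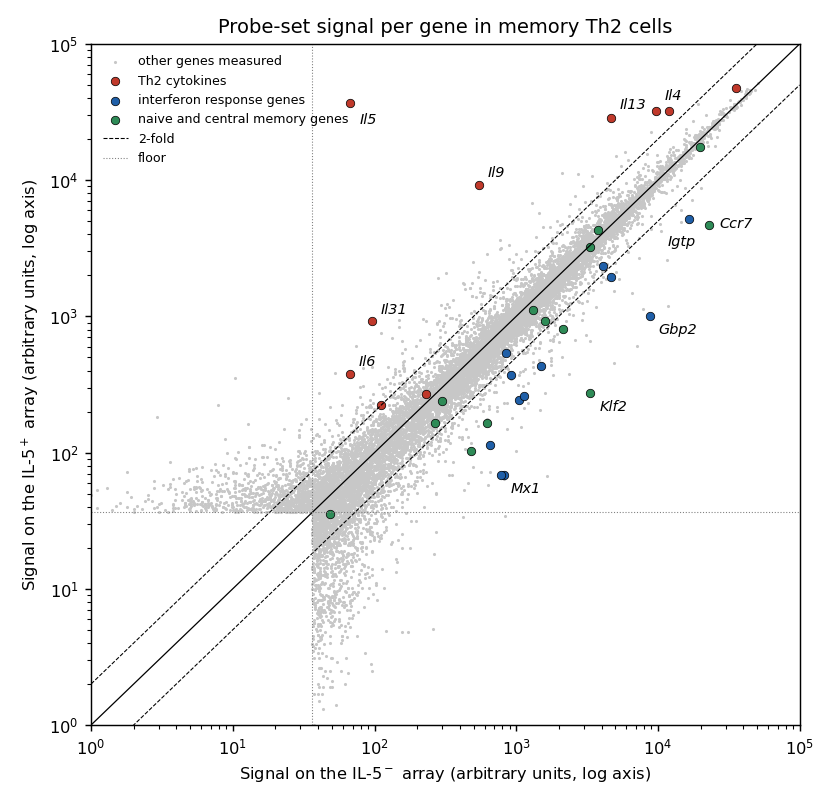
Signal of each measured gene on the IL-5- array (x axis) and the IL-5+ array (y axis), in arbitrary units on log axes, with the line of equality, 2-fold lines (dashed) and the floor of 36.3 (dotted). The Th2 cytokines lie above equality and the interferon response genes below it, while dim genes near the floor scatter widely on both sides.

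For gene lists fixed before the data were examined, the median log2 ratio of each list was set against 10000 random lists of the same size and brightness. Of the 33 lists, 31 had at least 4 measured members. The median lay at or above the 98th percentile of random lists in 8 and at or below the 2nd percentile in 6, where unrelated genes would give about 4% of lists outside these limits. Genes within a list are regulated together, so the percentiles describe these 2 arrays only.

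The Th2 cytokine list had the highest median, 2.12, above all random lists. Of its 10 measured members, 8 were at least 2-fold higher and none lower. The list includes Il5, on which the cells were sorted; without it the median was 1.74, above all random lists, and 7 of 9 were at least 2-fold higher. The median without Il5 was added after the data were seen, and it need not be independent of a sort on IL-5 production. Il24, named after its value was seen, only just reached 2-fold (221.6 against 110.5). Il5, Il9, Il31 and Il13 led the list. Among Th2 surface receptors (median 0.44, 99.9th percentile), 3 of 8 were at least 2-fold higher, namely Cysltr1 (1.52), a leukotriene receptor, Cd200r1 (1.07, and 0.93 with an added constant) and Ccr8. The receptor gene Il4ra was lower, at -1.09. With an added constant in place of the floor this list had a median of 0.22 at the 97.9th percentile and no longer stood apart. Th2 transcription factors did not stand apart as a list (median 0.063, 83.4th percentile). Pparg was the only member at least 2-fold higher, and Bhlhe40 had a log2 ratio of 0.55. Maf, which drives Il4, was at -1.01 with probe sets from -1.88 to -0.35 and came under 2-fold in each of the other scalings.

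Effector genes of other T helper programmes did not move in one direction. Th1 genes had a median of -0.39 (0.08th percentile), with 3 of 11 at least 2-fold lower and 2 higher. The lower ones were Tbx21, Eomes and, named after its value was seen, Il18r1 (-1.03), whereas Cxcr6 (10758 against 3423, 1.65) and Il18rap (1.19) were higher. The Th17 list (median 1.67, above all random lists) had only 4 measured members, of which Il17a (11242 against 2104, 2.42), Rora and Ahr (1.13) were at least 2-fold higher and Ccr6 stood at -0.45. The second Ahr probe set brought that gene's median to 0.20. In the cytotoxic and NK receptor list the median (0.25, 99.7th percentile) and the mean (-0.27) differed in sign, with 9 members above 0 and 8 below. None of its 17 members was at least 2-fold higher and 5 were lower. Gzmk (at least 4.72-fold), Gzma (-1.86), the chemokine gene Xcl1 (-1.68) and Gzmm (-1.27) were lower, as was Ctsw (-1.21), named after its value was seen. Gzmk and Gzmm were dim and lost the 2-fold difference with a higher floor and with an added constant, respectively. Tfh genes did not stand apart (median 0.035, 78.8th percentile), although 4 of 9 were at least 2-fold lower. Slamf6 (-1.63), Il21 (-1.28) and the signalling adaptor gene Sh2d1a (-1.25) led these. Cxcr5 was dim and above the floor only on the IL-5- array (85.1), and the 2 probe sets of Il21 disagreed (-1.28 and 0.44). Treg genes had a median of -0.25 (4.14th percentile), with Ikzf2 (-1.76), Itgae (-1.58) and Foxp3 (39.6 against 94.6) lower. The list's median was -0.41 at percentile 0.52 with a floor at the 20th percentile of signals, -0.41 at percentile 0.34 with no floor and -0.40 at percentile 0.12 with an added constant, so that it stood apart there. Foxp3 lay near the floor and stood at -0.79 with an added constant, and Itgae stood at -0.81 with a floor of 112.8 and at -0.44 at its other probe set. Nrp1 was higher at 1.77, although its probe sets ranged from -0.24 to 2.67.

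Interferon response genes were the lowest list (median -1.94, below all random lists). Of 12 measured members, 10 were at least 2-fold lower in IL-5+ cells and none higher. Ifit3, Mx1, Gbp2 and Rsad2 (113 against 655, -2.54) led it. Naive and central memory genes also lay below all random lists (median -0.70), with 5 of 13 at least 2-fold lower and 1, Bach2 (0.19), above 0. Bach2 and Lef1 (-1.42), one of the 5, are named after their values were seen. Beside Klf2 and Ccr7, these included the interleukin-6 receptor genes Il6ra (-2.24) and Il6st (-1.92), and all 3 measured Il6st probe sets were below -1. The second Il6ra probe set was at -0.18. Among other T cell cytokines (median 0.61), Tnfsf14 (1.88), Tnfsf10 (1.79), which encodes the death ligand TRAIL, and Tnfsf11 (14961 against 5075, 1.56), which encodes RANKL, were higher. Ltb, encoding lymphotoxin beta, was lower (2587 against 11608, -2.17).

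Other lists stood apart with few or no 2-fold members. All 13 unfolded protein response genes had ratios above 0 at their brightest probe set (median 0.34, 99.99th percentile), led by Creld2 (0.96), Herpud1 (0.86) and Dnajb9 (0.77). Ddit3, named after its value was seen, stood at 0.17 there but at -0.92 at its other measured probe set. Cholesterol synthesis genes had a median of 0.51, above all random lists, with Idi1 at 0.88 and Insig1 at 0.72, while Dhcr7 stood at -0.91. Cell cycle genes had a median of -0.48, below all random lists, and 17 of 19 were below 0, such as Mcm6 (-0.70) and Cdk1 (-0.64). Apoptosis genes had a median of -0.36 (0.66th percentile), with Bbc3 at -0.97, Bcl2 at -0.79 and Bcl2l11 at -0.71. T cell core genes had a median of -0.15 (0.39th percentile), with Cd247 at -0.81, Cd3g at -0.71 and Cd3d at -0.57. Immediate early genes had a median of 0.26 (99.98th percentile), and Fos (1.92), Ier3 (1.61), Fosl2 (1.05) and Fosb (1.02) were at least 2-fold higher. Fosl2 and Fosb came under 2-fold with an added constant. T cell activation genes did not stand apart (median 0.063, percentile 85.3), and Lag3, an inhibitory receptor gene, was the only member at least 2-fold apart (148 against 857, -2.54). Glycolysis, Polycomb and Trithorax, integrin and housekeeping lists had medians of -0.094, -0.17, -0.051 and 0.044 and did not stand apart. The integrin list did with a floor of 112.8 (-0.26, percentile 1.72), and the Polycomb and Trithorax list with the median of each gene's probe sets (-0.29, percentile 0.22). In the integrin list, Itgae and Itga6 (-1.17) were at least 2-fold lower, though Itga6 came just under 2-fold with the median of its probe sets.

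**Figure D3:**
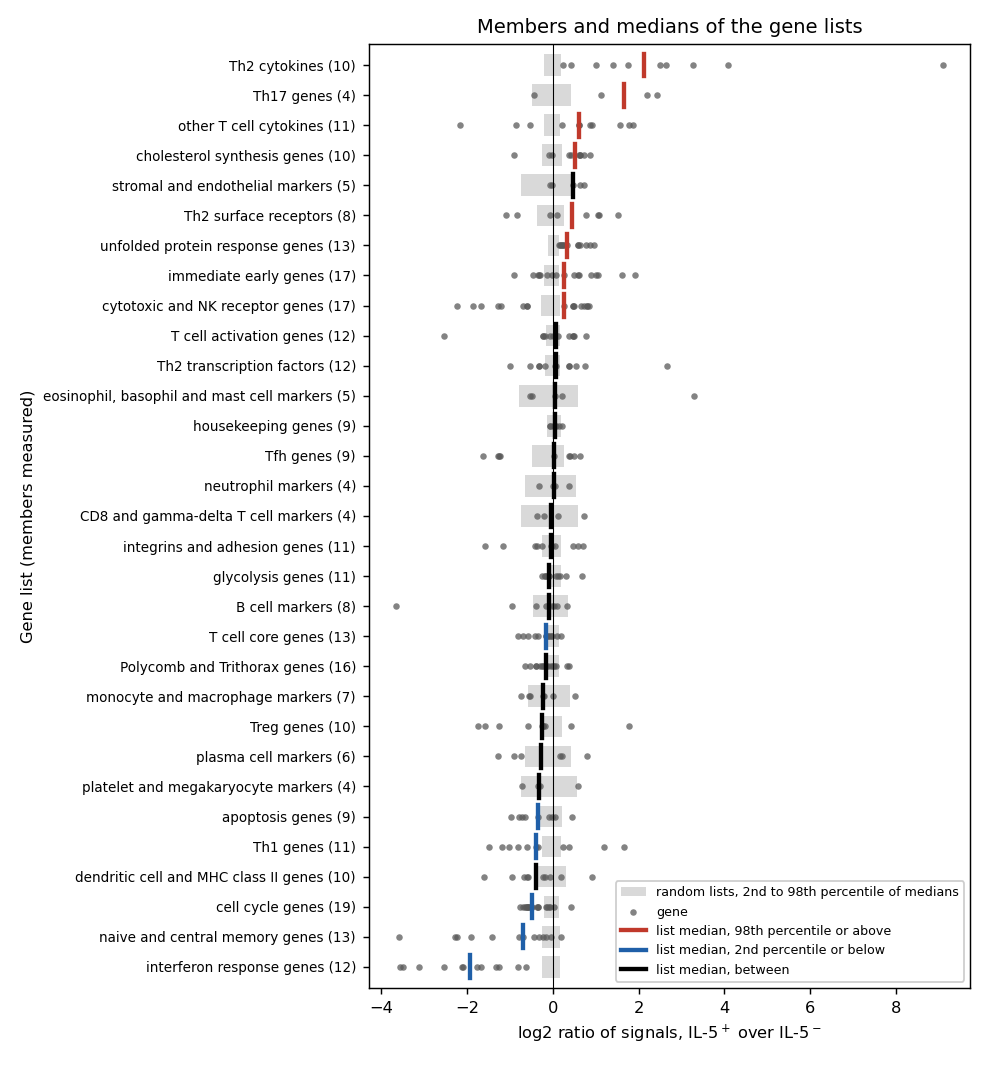
log2 ratio of signals (IL-5+ over IL-5-) of the measured members (points) and the median (vertical bar) of the 31 gene lists with at least 4 measured members, whose number is in parentheses. Grey bands span the 2nd to 98th percentile of medians of 10000 random lists, and the Th2 cytokines (2.12) and interferon response genes (-1.94) lie farthest outside them.

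Most markers of other cell types were dim on both arrays, with exceptions such as Ctss and Cd83, and none of these lists with a percentile stood apart. B cell markers had a median of -0.098. Ighm was lower in IL-5+ cells at its brightest probe set (64.4 against 813), but its probe sets ranged from -3.66 to 0.16 and their median was -0.64. Plasma cell markers had a median of -0.29, with Pou2af1 at -1.28. Monocyte and macrophage markers had a median of -0.24 and 8 of 15 were under the floor on both arrays. Their brightest member, Ctss, had signals of 2210 and 3279. Dendritic cell and MHC class II genes had a median of -0.40 at the 2.54th percentile, with H2-Aa at 51.0 and 156 and H2-Ab1 at 157 and 250. Its brightest member, Cd83, had signals of 2359 and 3508. This shift ran in the same direction as that of the interferon response genes, and it passed the 2nd percentile with a lower floor (percentile 1.81) and with an added constant (percentile 0.12), but not with no floor (-0.61, percentile 2.42). Without probe sets that may match several transcripts the median was -0.19, at percentile 20.4. That choice drops the probe sets used for H2-Aa, H2-Ab1 and Cd74, so it does not check the shift seen at them. H2-Aa stood at -0.47 with a floor of 112.8. Neutrophil, platelet, and CD8 and gamma-delta T cell markers had medians of 0.027, -0.32 and -0.044. Eosinophil, basophil and mast cell markers had a median of 0.050, and Hdc was their only member at least 2-fold apart. Stromal and endothelial markers had a median of 0.47 at the 96.9th percentile, from 5 members, the brightest of which was Pecam1 (258 and 165). NK cell and erythroid markers had only 2 and 3 measured members. With no floor and with an added constant, 7 NK cell markers entered, 5 of them under 36.3 on both arrays, and their list stood apart with medians of 3.02 (percentile 99.98) and 0.59 (percentile 99.8). The brightest NK marker was Fcer1g (61.4 and 4.70), and the brightest erythroid marker was Car2 (114 and 122).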

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

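The number of 2-fold genes depended on the treatment of dim signals. From 374 higher and 526 lower, it went to 1325 and 1572 with a floor at the 20th percentile, to 2057 and 2311 with no floor, and to 183 and 226 with a floor at the 60th percentile. Thresholds of 1.5-fold and 3-fold gave 1035 and 1560, and 91 and 143. The other 3 scalings, the added constant and both other choices of probe sets stayed within 1.5 times of each count, but division by the array median gave 435 higher and 443 lower genes (49.5% higher, against 41.6%). The log2 ratio of Il5 was 8.36 with the floor at the 60th percentile and 8.48 with the added constant, against 9.10, as both raise its dim IL-5- signal. The number of lists standing apart ranged from 7 to 9 for higher and from 6 to 8 for lower medians, with no list reversed. Of 264 list medians under the alternatives fixed beforehand, 7 newly stood apart (Treg in 3 alternatives, dendritic cell and MHC class II genes in 2, integrins and Polycomb in 1 each) and 1 no longer did (Th2 surface receptors). The NK cell markers, with too few measured members otherwise, stood apart higher with no floor (3.02) and with the added constant (0.59). Lists left with fewer than 4 measured members under an alternative, such as the Th17 genes without the suffixed probe sets, gave no value there. Of 75 named genes at least 2-fold apart besides Il5, 17 came under 2-fold in 1 or more alternatives, and none of the 75 changed sign. These counts cover only the alternatives in which a gene kept a value. A gene left without a ratio, such as Cxcr5 with a floor of 112.8, was not counted as lost there. No paired analysis was possible because each group has 1 array, and no replicate could be left out. Depth is not defined for arrays, and at mean signals under 112.8 the SD between probe sets (0.55) makes a 2-fold difference smaller than 2 SD.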

Other observations

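All families in the next 2 paragraphs were chosen after their values were seen, as were the tests of antigen-presenting and of resting T cells, each of which replaced earlier tests of the same explanation. The tests of loess and of dim genes were set before their results were seen. Interferon-inducible GTPases were lower in IL-5+ cells in all 12 measured members, each by at least 2-fold (median log2 ratio -2.13). They included Igtp (5194 against 16544), Ifi47 (6077 against 14634), Gbp6 (657 against 3294) and Irgm2 (470 against 1755). Among 22 measured chemokine genes, 4 were at least 2-fold lower, namely Cxcl10, Cxcl11 (at least 2.89-fold), Ccl22 (59.4 against 458) and Xcl1, and 2 higher, Cxcl2 and Cxcl3, both under the floor on the IL-5- array. Ccl1, Ccl3 and Ccl4 were bright on both arrays, with log2 ratios of 0.22, 0.50 and 0.48.

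Of 24 measured interleukin genes, 11, Il5 included, were at least 2-fold higher and 3 lower in IL-5+ cells. Of the higher genes, Il4, Il5, Il6, Il9, Il13, Il24 and Il31 are members of the Th2 cytokine list above. Il1a and Il23a, among the higher, and Il12a, among the lower, were above the floor on 1 array only. Il18 (539 against 156) was among the higher, Il16 (649 against 2008) among the lower, and Il2 was at 0.91 (36010 against 19128). The 3 probe sets of Il16 ranged from -1.76 to -0.47. Il21, also among the lower, had probe sets of opposite sign. Among 27 interleukin receptor genes, 1 was higher (Il18rap) and 5 were lower, namely Il21r (202 against 738), Il6ra, Il6st, Il4ra and Il18r1. Of 9 serpin B genes, which encode intracellular protease inhibitors, 5 were at least 2-fold higher and none lower, with Serpinb9, an inhibitor of granzyme B, at 14121 against 6147 and Serpinb6b at 6862 against 3063. The others were Serpinb9b, Serpinb6a and Serpinb1a. The matrix metalloproteinase genes Mmp13 (836 against 148) and Mmp10 (178 against 40.5) were higher among 9 measured. Among 4107 probe sets without a single gene name that were above the floor on both arrays, 6 were at least 4-fold higher and 15 at least 4-fold lower.

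The interferon response genes were the lowest list. A trend of the ratio with signal is argued against, because the list's median was -1.90 after loess. Antigen-presenting cells left in the IL-5- fraction would dilute T cell core genes there, but the median log2 ratio of these was -0.15, the opposite direction, while the 4 MHC class II transcripts were lower in IL-5+ cells (-0.65). These transcripts were dim on the IL-5- array, with Cd74 at 164 and H2-Ab1 at 250. Igtp reached 16544 there and 5194 on the IL-5+ array. Of 15 monocyte and macrophage markers, 8 were under the floor on both arrays. The brightest markers, Ctss (2210 against 3279) and Cd83 (2359 against 3508), were lower in IL-5+ cells, the direction such cells would give. Of the measured members, 5 monocyte and macrophage markers lay below 0 and 2 above. For dendritic cell and MHC class II genes it was 8 below and 2 above. The markers thus do not settle the share of such cells. Such cells cannot be told apart from a difference within the T cells, since the share needed is not known and 2 of 13 core genes lay above 0. A biological difference between the sorted fractions, such as their exposure to interferon, stays open and untested, as does any event in handling 1 of the 2 samples.

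Naive and central memory genes were also lower in IL-5+ cells. A candidate explanation is that the IL-5- fraction held more resting or naive T cells, which would dilute genes of cycling and activated cells there. The median log2 ratio of the cell cycle genes was -0.48, the opposite direction, with 2 of 19 above 0, and that of the T cell activation genes was 0.063, with members on both sides of 0. Extra resting cells cannot be told apart from a difference in memory state, since the share needed is not known and more cycling in the other IL-5- cells would hide a dilution.

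Noise near the floor may account for the 2-fold differences among dim genes. For the 295 called genes with a brighter signal under 112.8, 58.2% of 79 other probe sets of the same gene had the same sign (exact 95% interval 46.6 to 69.2%). The share was 86.0% of 186 at brighter signals up to 500 and 94.3% of 279 above that. By the choice of probe set, the others were dimmer on average than the one called, so their disagreement may partly be their own noise. The interval treats probe sets of the same gene as independent. Whether dim genes differ between the fractions stays open for single genes.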
